A study of Mus musculus with 33 samples.

How the data were processed

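Gene expression was measured by RNA sequencing in 30 libraries of mouse NK cells, and 3 further samples of the series were chromatin accessibility libraries. Per the labels' protocols, RNA was amplified with a full-length single-cell mRNA kit from 5 ng of total RNA and libraries were made by transposase tagmentation. The labels describe no molecular barcodes, no strand setting, no sorting gate and no annotation release. Per the labels' protocols, the ex vivo cells were liver single-cell suspensions in RPMI 1640 with 10% fetal bovine serum at 37 °C, whereas the unstimulated libraries carry the treatment label of no treatment. HISAT2 2.1.0, featureCounts, Subread and Trimmomatic with the genome build mm10 are named in the submitters' processing notes without their options.

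The deposited values were raw counts per Ensembl gene, 1 column per library, whole numbers whose totals differ between libraries. The tissue panel files listed 54446 genes and the ex vivo files 55401, of which 54100 were shared, so each experiment was tested within its own table. Symbols came from the files' identifiers matched to a table of gene names, which held 54409 and 55141 of them. Coordinates are those of GRCm38, the assembly of mm10. Members of gene families with similar sequences (Ly49 receptors, granzymes, Ifit genes, globins) share reads, and their separate counts are uncertain to that extent.

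Libraries were grouped by the organ, cell type and treatment in the labels, 2 per group. The 2 accessibility samples whose title and source contradict each other were put in no group; the 3 accessibility samples were not analysed here. Tests used R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Within each experiment, genes passed filterByExpr (17406 in the tissue panel, 15959 ex vivo), totals were scaled by TMM, and 1 quasi-likelihood model with robust dispersions was fitted over all groups, with 7 and 8 residual degrees of freedom. Benjamini-Hochberg adjustment was made within each comparison over all genes tested, and the threshold was an adjusted p of 0.05. The 20 comparisons were contrasts of this model, and those called interactions test the difference between 2 differences. Standard errors were derived from the F statistic. Fold changes against groups without counts are given as at least the fold that 3 counts per library would give; such floors, like the errors of counting, cover counting error only.

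CPM with an SD are scaled by TMM factors; summed levels of gene lists are CPM of library totals. For named genes, a rule fixed before the data were examined took, per comparison, up to 8 genes per direction with the largest log2 fold change among those past the threshold, with a mean of at least 20 CPM in the higher group and no overlap between libraries. It left out predicted and unnamed genes, pseudogenes, mitochondrial genes and receptor segments. It added the 4 members of each gene list with the smallest adjusted p and 30 preset NK genes. The text gives a selection of these genes, favouring those whose call does not rest on 1 library, a choice made after the data were examined, as were the sex-linked genes Xist and Ddx3y.

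Gene lists were written from general knowledge before the data were examined. They covered residency and ILC1 markers, circulating and mature NK markers, Ly49 receptors, other NK receptors and adaptors, checkpoint receptors, cytotoxic granule and death ligand genes, and cytokine and chemokine genes. Response lists covered immediate early and NF-kB, NFAT and AP-1 target genes, IL-18 and MyD88 pathway genes, interferon-stimulated genes, unfolded protein response genes, heat shock genes, cell cycle genes, glycolysis genes, cholesterol synthesis genes, lymphocyte transcription factors and TGF-beta-linked genes. Lists for other cells covered T cell markers, other ILC markers, B and plasma cell markers, macrophage and dendritic cell markers, neutrophil markers, hepatocyte markers, salivary epithelium markers, stromal, endothelial and epithelial markers, and erythroid and platelet markers. Each list was tested against all other genes with limma's camera on log2 CPM (prior count 2) with an inter-gene correlation of 0.01, adjusted over all 27 lists of a comparison, of which 1 is not reported here, as is 1 gene. The correlation estimated from the data was an alternative, and where a call was lost with it that value is printed; calls of camera printed without such a value also held with the estimated correlation. Counts adjusted over the list alone repeat the adjustment among its members.

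The scripts were tested on simulated counts with 200 changed genes per comparison. For the liver comparison (16282 genes) edgeR recovered 8% of 2-fold and 64% of 4-fold changes with 2.7% false calls, and DESeq2 18% and 80% with 50.3% false calls. For the interaction of salivary glands and liver (16263 genes) edgeR recovered 0% and 21% with 16% false calls, and DESeq2 1% and 51% with 57% false. For PI in cNK (14251 genes) edgeR recovered 100% of both with 2.91% false calls, and 0% and 48% with the spread of the tissue panel. For the interaction with PI (14208 genes) edgeR recovered 99% and 100% with 6.13% false calls, and the panel spread recovered 0%. Camera called the changed list in each of these 4 simulations and 0 of 20 unchanged lists in each. The simulated genes were drawn independently of each other, so this check does not cover lists whose members are correlated. Changed genes had a mean of at least 20 CPM, and each simulation used the spread between the libraries of its own experiment. The ex vivo rates thus hold for that spread only, which may be technical, and not for a spread between animals. In the data 67.4% of genes were called for PI in cNK, far more than were changed here.

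Alternatives planned before the data were examined were DESeq2, RLE size factors, no filter on low counts, a fit of the compared groups only, the replicate number as a block, and leaving out each library in turn. Added after the data were examined were leaving out each library for the genes shared by 3 organs, and the spread of the tissue panel for the ex vivo experiment: libraries were summed per group and tested by likelihood ratio in edgeR with the gene-wise dispersions of the panel. For 1883 genes without such a dispersion the trend was used. Between the 2 libraries of each panel group this test called 0 genes, with 266 to 952 below an unadjusted p of 0.05. The dispersions were measured on these same libraries, so few calls were likely in advance. This outcome therefore does not measure the false calls of the test. DESeq2 was not run on these pairs.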

Results

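RNA sequencing of mouse natural killer (NK) cells was examined in 30 libraries, which formed 15 groups of 2. Conventional NK cells (cNK) circulate through blood and organs, whereas tissue-resident NK cells (trNK) stay within an organ. The tissue panel held 14 libraries in 7 groups: cNK and trNK of the liver, salivary glands and uterus, and cNK of the spleen. The ex vivo experiment held 16 libraries in 8 groups of liver cNK and trNK. These liver cells were left unstimulated or received the phorbol ester PMA (50 ng/mL) with the calcium ionophore ionomycin (1 µg/mL), a pair written PI here, for 5 h. PI was given alone, with the cytokine IL-18 (10 ng/mL) or with the cytokine IL-21 (20 ng/mL), and the secretion blocker Brefeldin A was added after 1 h. The labels state no sorting gate for either cell type. Genes of the sorting markers may differ because of the sort itself, and these markers are not named in the labels. Per their protocols the ex vivo cells were liver single-cell suspensions, so other liver cells may have been present during treatment. Whether a change in cNK or trNK came through such cells was not tested. Total counts per library ran from 11.8 to 25.4 M in the tissue panel (median 20.8 M) and from 22.9 to 44.1 M ex vivo (median 30.3 M). The 3 chromatin accessibility samples of the series were not analysed here.

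The 2 libraries of a group differed far less ex vivo than in the tissue panel. The common biological coefficient of variation (edgeR) was 0.848 in the panel and 0.0756 ex vivo. The labels do not say whether the libraries of a group came from separate animals, so p-values measure only the spread between these libraries, which may be technical. For this reason each ex vivo total of called genes, and the count of some lists, is also given with the gene-wise spread of the tissue panel, an alternative chosen after the data were examined. Values after ± are standard errors for log2 fold changes and SD (n = 2) for CPM, the counts of a gene per 1e6 counts of its library. A gene was called higher or lower where the adjusted p of edgeR's quasi-likelihood test was below 0.05.

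How trNK differ from cNK within one organ was first examined in the liver. Liver trNK carried more transcripts of residency genes. Itga1, which encodes the integrin subunit CD49a (chromosome 13, 114958079 to 115101964, mm10), stood at 555.1 ± 37.0 CPM in trNK and 3.22 ± 0.0177 CPM in cNK (log2 fold change 7.42 ± 0.644, adjusted p = 4.13e-05). Zfp683, which encodes the residency transcription factor Hobit, was higher by 7.96 ± 0.871 on the log2 scale (adjusted p = 0.000233), and the death ligand gene Tnfsf10 by 4.70 ± 0.433 (adjusted p = 5.71e-05). Of 19 residency and ILC1 markers, 9 were higher and 0 lower, or 15 and 0 adjusted over the list alone (camera adjusted p = 1.17e-12; adjusted p = 0.013 with an estimated correlation). Cxcr6, a chemokine receptor gene of the same list, stood at 1677 ± 105 CPM in trNK and 4.38 ± 5.97 CPM in cNK without passing the test (adjusted p = 0.103; DESeq2 adjusted p = 1.35e-05). Among 12 checkpoint receptors, 6 were higher and 0 lower, or 9 and 0 adjusted over the list alone (camera adjusted p = 7.93e-11). The inhibitory receptor gene Tigit was higher by 2.09 ± 0.297 (adjusted p = 0.00139). Pdcd1, which encodes PD-1, was at least 339-fold higher (42.0 ± 9.22 CPM against no counts, adjusted p = 0.00839). Il21r, the IL-21 receptor gene, stood at 544.4 ± 37.2 CPM in trNK and 54.3 ± 5.66 CPM in cNK (log2 fold change 3.33 ± 0.388, adjusted p = 0.000352).

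Genes of mature circulating NK cells were lower in liver trNK. Eomes, a T-box transcription factor gene (chromosome 9, 118478186 to 118486132), fell from 170.5 ± 13.3 CPM in cNK to 0.245 ± 0.138 CPM in trNK (log2 fold change -9.40 ± 0.361, adjusted p = 1.63e-08). The inhibitory or activating receptor genes of the Ly49 family had 1 member higher and 5 lower of 10, or 1 and 8 adjusted over the list alone (camera adjusted p = 4.97e-09). Klra4 (log2 fold change -11.70 ± 0.476) was among the lower members and Klra5 (4.30 ± 0.53) was the higher one. Of 14 circulating and mature NK markers, 0 were higher and 10 lower, or 1 and 12 adjusted over the list alone (camera adjusted p = 4.49e-20). The transcription factor gene Zeb2 changed by -5.40 ± 0.424 and Itga2, which encodes CD49b, by -2.90 ± 0.341. Both IL-18 receptor genes were lower, Il18r1 by -4.72 ± 0.361 and Il18rap by -2.78 ± 0.285. The pore-forming granule gene Prf1 changed by -1.86 ± 0.261, while Gzma was at 9948 ± 2266 CPM in trNK and 10600 ± 805 CPM in cNK. Granzyme B (Gzmb) was higher by 2.55 ± 0.436 (adjusted p = 0.00755), a call that ended without liver cNK replicate 1 or 2 (adjusted p = 0.358 and 0.227) and without liver trNK replicate 1 or 2 (adjusted p = 0.214 and 0.142). Ifng did not pass the test (331.4 ± 64.5 against 322.9 ± 73.9 CPM, adjusted p = 1). Cell cycle genes had 2 of 22 lower, or 8 adjusted over the list alone (camera adjusted p = 5.5e-07; adjusted p = 0.256 with an estimated correlation). Some markers of other cells moved with liver trNK. Summed T cell markers were 5132 and 4458 CPM in its libraries against 1360 and 1190 CPM in liver cNK, a list that did not pass the camera test. The neutrophil marker Mmp9 stood at 150.6 ± 17.0 CPM against no counts. S100a8 and S100a9, of the same list, stood at 0 and at most 0.04752 CPM in liver trNK. Macrophage and dendritic cell markers were at 718.3 and 1224 against 291 and 306.6 CPM, with 1 of 12 higher, or 3 adjusted over the list alone. At 664.5 and 2540 against 429.3 and 368.6 CPM, B and plasma cell markers had 0 of 12 called (camera adjusted p = 0.171). Stromal, endothelial and epithelial markers were at 184.5 and 128.3 against 69.3 and 53.4 CPM with 1 of 12 higher, and the counts of these last 2 lists did not move adjusted over the list alone.

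Over all 17406 genes tested, 468 differed between liver trNK and cNK, 200 higher and 268 lower in trNK. DESeq2 called 1202 genes, a fit without the filter on low counts 1012, and a fit of the compared groups alone 187. The last fit kept 161 of the 468 calls, and 55.6% of its calls were higher in trNK against 42.7% in the main fit.

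The same question was asked in the salivary glands. Rgs1, a regulator of chemokine receptor signalling, was higher in trNK (3403 ± 46.0 against 949.5 ± 166 CPM, log2 fold change 1.84 ± 0.201, adjusted p = 0.00285), as was the actin and membrane signalling gene Swap70 (2.78 ± 0.407, adjusted p = 0.00956). Eomes was lower in trNK at 107.4 ± 22.4 CPM against 387.3 ± 15.1 CPM (log2 fold change -1.85 ± 0.237, adjusted p = 0.0046), together with Itga2 (-2.23 ± 0.333), Il18r1 (-2.29 ± 0.325), Il18rap (-1.94 ± 0.276) and the glycolysis gene Pfkp (-1.91 ± 0.241). Residency and ILC1 markers had 4 higher and 0 lower of 19, or 11 and 0 adjusted over the list alone (camera adjusted p = 2.63e-13; adjusted p = 0.0321 with an estimated correlation). Among them Itga1 was higher by 3.77 ± 0.541 (adjusted p = 0.00928), Zfp683 by 4.45 ± 0.738 (adjusted p = 0.0215) and Tnfsf10 by 2.28 ± 0.388 (adjusted p = 0.0253). These 3 calls ended without salivary gland cNK replicate 1 (adjusted p = 0.5, 0.286 and 0.0578) and without cNK replicate 2 (0.371, 0.14 and 0.0557). Without trNK replicate 2 Itga1 and Zfp683 were not called (0.13 and 0.0543), and without trNK replicate 1 Itga1 was not (0.0968). Itgae, which encodes the integrin subunit CD103, stood at 211.4 ± 59.3 against 5.57 ± 0.395 CPM and Cxcr6 at 843.8 ± 393 against 0.983 ± 0.125 CPM, with adjusted p = 0.53 and 0.271 (DESeq2 adjusted p = 0.0419 and 2.59e-06). TGF-beta-linked genes had 1 higher of 17, or 6 higher and 2 lower adjusted over the list alone (camera adjusted p = 3.86e-05; adjusted p = 0.0321 with an estimated correlation). Circulating and mature NK markers had 3 of 14 lower, or 8 adjusted over the list alone (camera adjusted p = 1.07e-05; adjusted p = 0.0733 with an estimated correlation). Macrophage and dendritic cell markers moved with the trNK libraries: their summed level was 1076 and 1386 CPM against 433.3 and 496.1 CPM in cNK, with 0 of 12 called, or 1 higher adjusted over the list alone (camera adjusted p = 1.07e-05; adjusted p = 0.153 with an estimated correlation). In these libraries B and plasma cell markers were at 1651 and 2359 against 665.4 and 816.3 CPM, with 0 of 12 called either way (camera adjusted p = 0.934), a median log2 fold change above 0 and a mean below 0. Stromal, endothelial and epithelial markers were at 273 and 288.6 against 84.4 and 96.4 CPM, with 0 of 12 called, or 2 higher adjusted over the list alone (camera adjusted p = 0.147). Salivary gland trNK replicate 2 stood apart: rRNA made up 1.27% of its counts against 0.388 to 0.463% in the other 3 gland libraries, mitochondrial genes 2.21% against 1.40 to 1.63%, and Mucl2, a gene of salivary secretion, 3.08% against 1.63 to 1.76%. Without it 45 genes were called, 29 of them also in the main fit. In all, 45 genes differed, 20 higher and 25 lower. The share of calls that were higher was 44.4%, but 25.4% of 118 calls without salivary gland trNK replicate 1 and 80.8% of 26 calls in a fit of the compared groups alone, which kept 11 of the 45. DESeq2 called 284 and a fit without the low-count filter 297. In the compared groups alone Swap70, Il18rap and Eomes (each 0.052), Pfkp (0.0666) and Itga2 (0.14) lost their calls.

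In the uterus, trNK had higher transcripts of the neuropeptide receptor subunit gene Ramp1 (97.5 ± 40.4 against 5.82 ± 0.43 CPM, log2 fold change 4.07 ± 0.401, adjusted p = 0.000446), the oxysterol receptor gene Gpr183 (4.95 ± 0.659, adjusted p = 0.00248), Tnfsf10 (3.15 ± 0.405, adjusted p = 0.00201), the NK receptor gene Cd96 (1.70 ± 0.298) and Rgs1 (1.57 ± 0.2). Lower in trNK were Il18rap (-3.54 ± 0.295, adjusted p = 0.000283), Il18r1 (-3.29 ± 0.341), Itga2 (-2.78 ± 0.34), Zeb2 (-3.64 ± 0.389), the T-box factor gene Tbx21 (177.5 ± 50.9 against 512 ± 20.1 CPM, -1.53 ± 0.227) and Prf1 (-1.66 ± 0.259). Eomes did not pass the test (188.6 ± 9.06 against 242.7 ± 39.2 CPM, adjusted p = 0.658). Residency and ILC1 markers had 7 higher and 0 lower of 19, or 13 and 0 adjusted over the list alone (camera adjusted p = 1.86e-11; adjusted p = 0.0262 with an estimated correlation). Itga1 was one of them (3.91 ± 0.545, adjusted p = 0.00309), a call that ended without uterus cNK replicate 1 or 2 (adjusted p = 0.221 and 0.223) and without uterus trNK replicate 1 or 2 (adjusted p = 0.0746 and 0.0984). Circulating and mature NK markers had 6 of 14 lower, or 12 adjusted over the list alone (camera adjusted p = 2.13e-16). Of 20 other NK receptors and adaptors 1 was higher and 5 lower, or 3 and 8 adjusted over the list alone; Klrc1, which encodes NKG2A, changed by -1.43 ± 0.195 and Klrb1c, which encodes NK1.1, by -1.11 ± 0.154. Gzma was lower by -4.04 ± 0.429 (adjusted p = 0.00112), a call that ended without uterus cNK replicate 2 (adjusted p = 0.0585). The summed markers of 2 other cell groups stood higher in uterus trNK, and neither list passed the test. B and plasma cell markers had 1 higher and 0 lower of 12, or 1 and 1 adjusted over the list alone (camera adjusted p = 0.965; median 0.13, mean -1.05), and their summed level was 842.3 and 585.6 CPM against 381.1 and 194 CPM in uterus cNK. The immunoglobulin gene Ighm was the one called (603.7 ± 247 against 195.7 ± 19.7 CPM, adjusted p = 0.0118). Stromal, endothelial and epithelial markers had 1 and 0 of 12, or 2 and 0 adjusted over the list alone (camera adjusted p = 0.106; median 0.35, mean -0.18), with 268.3 and 221.2 against 69.3 and 96.7 CPM. Mitochondrial genes made up 1.725 and 1.366% of counts in uterus trNK against 1.005 and 1.055% in uterus cNK. For ribosomal protein genes the shares were 5.967 and 6.573% against 3.672 and 3.95%. In all, 189 genes differed, 79 higher and 110 lower. Without uterus trNK replicate 1 the count was 441, and without uterus cNK replicate 1 it was 126. DESeq2 called 679, of which 51.1% were higher against 41.8% in the main fit, a fit without the low-count filter 533 and edgeR on the compared groups alone 0, so that no gene named here was called in that fit.

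A shared trNK profile was sought as genes called in the same direction in all 3 organs, and 23 genes met this. The 12 higher genes were AU020206, Gcsam, Gm36723, Itga1, Lgals3, Ntan1, Rgs1, S100a6, Swap70, Tmem273, Tnfsf10 and Zfp683. Among the 11 lower genes were Adamts14, Cd247, Cmah, Coro7, Flna, Il18r1, Il18rap, Itga2, Pfkp and Rasgrp2. If CD49a or CD49b was used to sort the cells, Itga1 and Itga2 may restate the sort, which was not tested. Cd247 encodes the CD3 zeta signalling adaptor and changed by -1.21 ± 0.203 in liver, -1.62 ± 0.206 in salivary glands and -1.28 ± 0.203 in uterus. Lgals3, which encodes galectin 3, was higher by 2.45 ± 0.405, 2.25 ± 0.401 and 3.41 ± 0.422. Independent lists of these sizes would share 0.00104 higher and 0.00243 lower genes. The comparisons came from the same fit and shared each gene's spread. Genes with a small spread are thus more readily called in all 3, and these numbers are no chance level. Across all 17406 genes, which are not independent replicates, the log2 fold changes of liver and salivary glands correlated with Pearson r = 0.144 and Spearman rho = 0.138. DESeq2 gave 75 such genes, no low-count filter 102, and the edgeR fits of compared groups alone 0, since the uterus had no call there; leaving out single libraries gave 16 to 23.

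**Figure D1:**
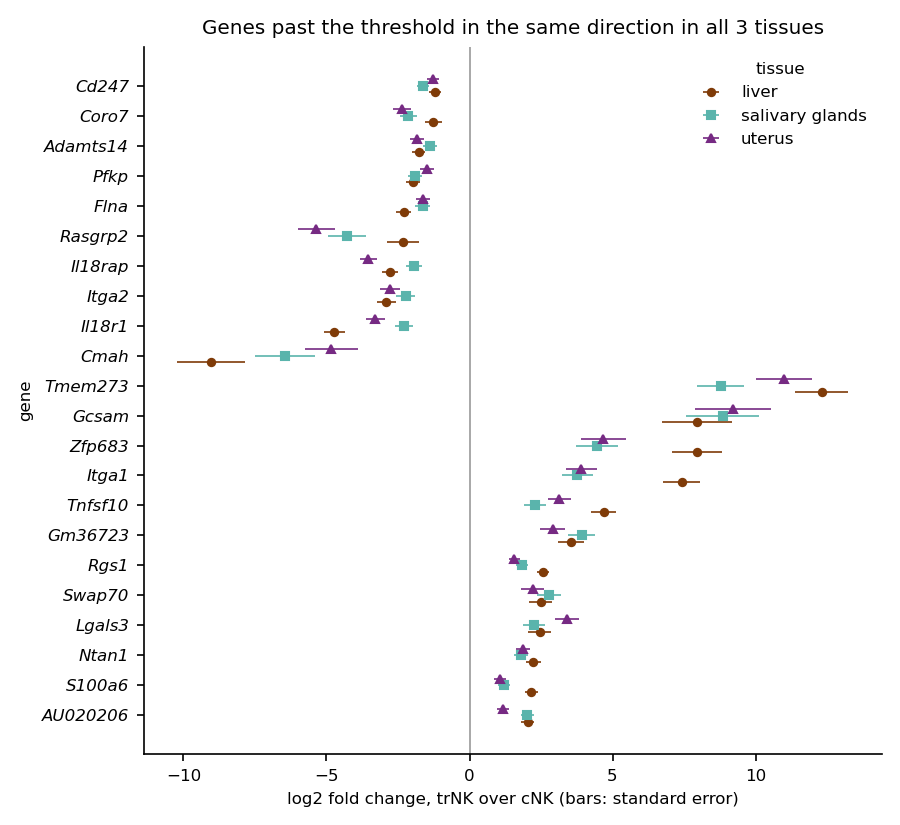
Log2 fold change of trNK over cNK (horizontal axis) for genes called in the same direction in liver, salivary glands and uterus, with standard errors as bars and 1 symbol per organ. Itga1 ranged from 3.77 in salivary glands to 7.42 in liver and Il18r1 from -4.72 in liver to -2.29 in salivary glands.

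**Figure D2:**
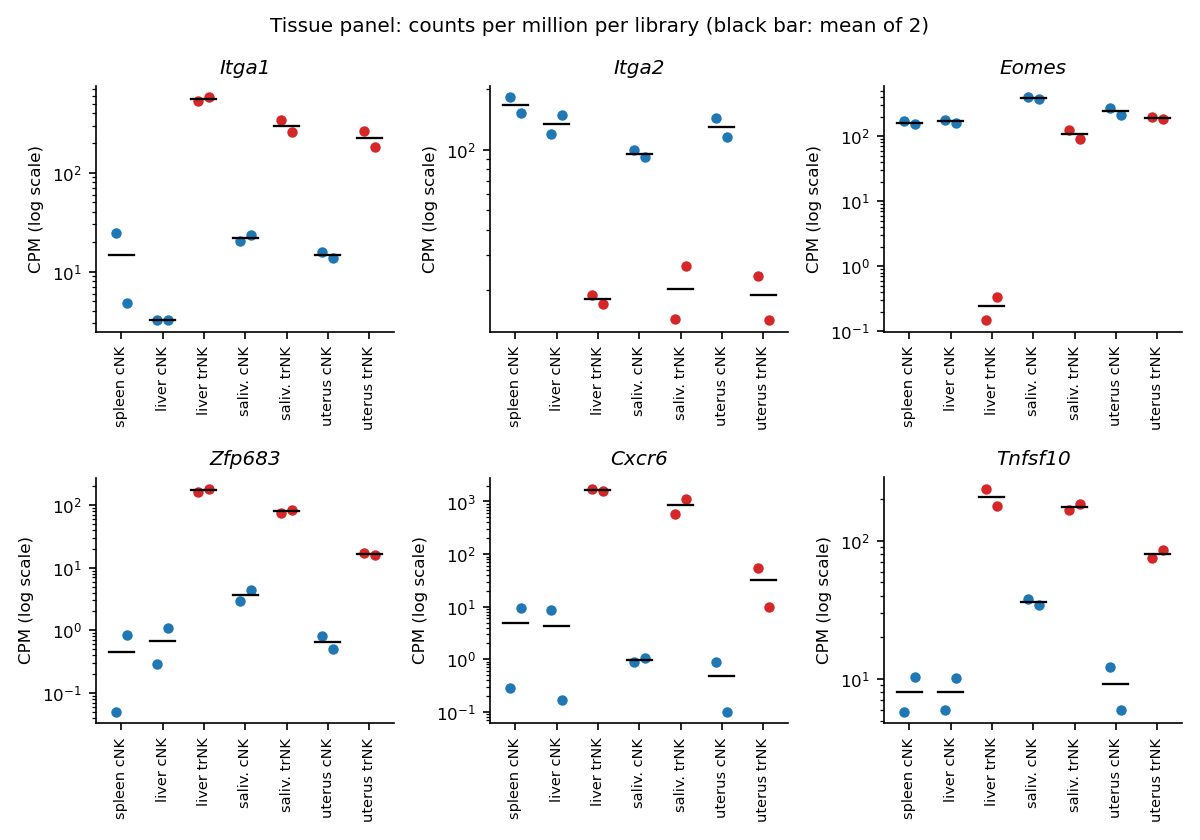
CPM (log axis, scaled with TMM factors) of 6 marker genes in each tissue-panel library, 2 dots per group with their mean as a black bar, cNK in blue and trNK in red. Eomes stood at 0.245 CPM in liver trNK and at 107.4 and 188.6 CPM in trNK of salivary glands and uterus.

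Whether the trNK-cNK difference itself differed between organs was tested as an interaction. Between salivary glands and liver, Eomes differed by 7.55 ± 0.412 on the log2 scale (adjusted p = 7.5e-07): it was almost absent in liver trNK and lower without being lost in salivary gland trNK. Klra4, an Ly49 receptor gene (chromosome 6, 130043730 to 130067301), differed by 10.74 ± 0.527 (adjusted p = 3.78e-07), with 1037 ± 247 CPM in salivary gland trNK and 0.441 ± 0.209 CPM in liver trNK. Zeb2 differed by 4.50 ± 0.523 (adjusted p = 0.0015) and Il18r1 by 2.43 ± 0.446 (adjusted p = 0.0384). The chemokine receptor gene Cxcr3 went the other way (-3.77 ± 0.404, adjusted p = 0.000653): it stood at 825.4 ± 40.2 CPM in liver trNK against 128 ± 44.0 CPM in liver cNK, and at 144 ± 3.63 against 305.2 ± 1.18 CPM in the salivary glands. Of 14 circulating and mature NK markers 5 had a positive interaction and 0 a negative one, or 8 and 1 adjusted over the list alone (camera adjusted p = 4.44e-12; adjusted p = 0.0174 with an estimated correlation). Ly49 receptors had 5 of 10 positive, or 7 positive and 1 negative adjusted over the list alone (camera adjusted p = 1.13e-08; adjusted p = 0.0174 with an estimated correlation). In all, 56 genes had an interaction, 44 positive and 12 negative. The share of positive ones was 78.6%, but 45.5% of 156 without liver cNK replicate 2, 53.6% of 405 with DESeq2 and 57.3% of 419 without the low-count filter. The count was 139 without liver trNK replicate 2 and 106 without salivary gland trNK replicate 1, and 35 in the 4 compared groups alone.

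Between uterus and liver, Eomes differed by 9.04 ± 0.418 (adjusted p = 9.2e-08) and Klra4 by 11.51 ± 0.534 (adjusted p = 9.2e-08), with Klra4 at 1090 ± 311 CPM in uterus trNK. Klrc1 differed by -2.37 ± 0.275 (adjusted p = 0.00111): it was at 334.1 ± 7.66 CPM in uterus trNK against 896.9 ± 156 CPM in uterus cNK, and at 1903 ± 248 against 988 ± 196 CPM in liver. The gut-homing integrin gene Itgb7 differed by -3.84 ± 0.53 (adjusted p = 0.00485) and the chemokine gene Ccl4 by -1.88 ± 0.296 (adjusted p = 0.0099). Thy1, a surface glycoprotein gene, differed by 2.62 ± 0.501 (adjusted p = 0.0349). Cell cycle genes had 3 of 22 positive and 0 negative, or 9 and 0 adjusted over the list alone (camera adjusted p = 4.5e-07; adjusted p = 0.344 with an estimated correlation). The centromere gene Cenpa was among them (3.37 ± 0.592, adjusted p = 0.0223), at 233.6 ± 5.27 CPM in uterus trNK and 18.1 ± 2.34 CPM in liver trNK. The summed level of the list was 2299 and 7098 CPM in uterus trNK replicates 1 and 2, 2626 and 3009 CPM in uterus cNK, 949.1 and 1025 CPM in liver trNK and 1582 and 2047 CPM in liver cNK. Ly49 receptors had 5 positive and 1 negative of 10, or 7 and 1 adjusted over the list alone (camera adjusted p = 4.5e-07; adjusted p = 0.0368 with an estimated correlation). In all, 107 genes had an interaction, 73 positive and 34 negative. The count was 318 without uterus trNK replicate 1 and 260 without liver cNK replicate 2; DESeq2 gave 610, no low-count filter 544 and the 4 compared groups alone 53, without Cenpa (0.067), Ccl4 (0.0705) and Thy1 (0.0994).

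Between uterus and salivary glands, edgeR called 0 genes with an interaction, with 986 at an unadjusted p below 0.05 and 115 called by DESeq2. The lowest adjusted p was 0.0794. Klrc1 was among the genes at that value (-1.92), and so was Ccl4 (-1.95); DESeq2 called both (adjusted p = 5.99e-08 and 6.9e-07). Of 14 circulating and mature NK markers 0 were called over all genes, and 1 positive and 6 negative adjusted over the list alone (camera adjusted p = 0.000755; adjusted p = 0.69 with an estimated correlation). Of 8 fits without 1 library, 7 gave calls: 51 without uterus trNK replicate 1, 41 without salivary gland trNK replicate 1, 18 and 12 without uterus cNK replicates 1 and 2, 14 without uterus trNK replicate 2, and 5 and 4 without salivary gland cNK replicates 1 and 2. Without salivary gland trNK replicate 2 there were 0. Without the low-count filter there were 151, and in the 4 compared groups alone 1.

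How cNK of an organ differ from cNK of the spleen was tested next, and the liver came first. Rgs1 was higher in liver cNK (409.4 ± 70.6 against 167.4 ± 19.1 CPM, log2 fold change 1.29 ± 0.198, adjusted p = 0.0353), and so were the receptor gene Lilr4b (2.13 ± 0.304, adjusted p = 0.0254) and the phosphatase gene Ppp1cc (1.74 ± 0.247, adjusted p = 0.0254). Igkc, the immunoglobulin kappa constant gene of B cells, was lower in liver cNK (0.145 ± 0.205 against 123.4 ± 38.0 CPM, log2 fold change -9.67 ± 1.1, adjusted p = 0.0123). B and plasma cell markers had 1 of 12 lower, or 3 adjusted over the list alone (camera adjusted p = 1.39e-13; adjusted p = 0.00202 with an estimated correlation), and their summed level was 429.3 and 368.6 CPM in liver against 1352 and 1482 CPM in the spleen libraries. Macrophage and dendritic cell markers were at 291 and 306.6 against 530.8 and 428 CPM, with 0 of 12 called either way. Immediate early and NF-kB, NFAT and AP-1 target genes had 0 of 32 called, or 3 higher adjusted over the list alone (camera adjusted p = 3.53e-06; adjusted p = 0.2 with an estimated correlation). In all, 13 genes differed, 11 higher and 2 lower in liver. With the replicate number as a block edgeR called 2 genes, 1 of them among these 13. Igkc kept its call there (adjusted p = 0.028), and Rgs1, Lilr4b and Ppp1cc did not (adjusted p = 0.0691, 0.051 and 0.051). The share of higher genes was 84.6%, but 40.7% of 108 without liver cNK replicate 2, 59.7% of 278 with DESeq2 and 61.9% of 291 without the low-count filter. The count was 39 without liver cNK replicate 1, 44 and 99 without spleen cNK replicates 1 and 2, and 0 in edgeR on the compared groups alone, so that no gene named here was called in that fit.

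Salivary gland cNK differed from spleen cNK in 419 genes, 321 higher and 98 lower. Immediate early and NF-kB, NFAT and AP-1 target genes had 11 of 32 higher and 0 lower, or 16 and 0 adjusted over the list alone (camera adjusted p = 1.86e-10; adjusted p = 0.051 with an estimated correlation). Myc was higher by 2.41 ± 0.313 (adjusted p = 0.00133), and so were Cd69, an activation and retention receptor gene (556 ± 135 against 124.3 ± 0.561 CPM, 2.16 ± 0.307, adjusted p = 0.00228), and the cytokine signalling inhibitor gene Socs1 (3.43 ± 0.375, adjusted p = 0.000545). Residency and ILC1 markers had 6 of 19 higher, or 10 adjusted over the list alone (camera adjusted p = 4.87e-05; adjusted p = 0.0844 with an estimated correlation), with Rgs1 at 2.50 ± 0.206 (adjusted p = 0.000115) and Tnfsf10 at 2.16 ± 0.391. Tbx21 was lower (173.4 ± 24.0 against 530.3 ± 56.7 CPM, -1.61 ± 0.228, adjusted p = 0.00228), as were Zeb2 (-2.40 ± 0.368) and Klrc1 (-1.70 ± 0.197). Eomes was higher by 1.27 ± 0.233 (adjusted p = 0.0113), a call that ended without spleen cNK replicate 2 (adjusted p = 0.0659). Salivary epithelium markers moved with these libraries: 2 of 11 were higher, or 7 adjusted over the list alone (camera adjusted p = 3.73e-10; adjusted p = 0.0593 with an estimated correlation). Their summed level was 6594 and 7141 CPM against 3.99 and 4.69 CPM in spleen cNK. Klk1b26, a kallikrein gene of salivary ducts, was at least 275.4-fold higher, and the B cell gene Ms4a1 at least 237.2-fold lower. Of the 12 B and plasma cell markers 1 was lower, or 4 adjusted over the list alone (camera adjusted p = 0.000144; adjusted p = 0.051 with an estimated correlation), at 665.4 and 816.3 against 1352 and 1482 CPM. Stromal, endothelial and epithelial markers had 2 of 12 higher, or 3 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.007; adjusted p = 0.0782 with an estimated correlation), and hepatocyte markers 0 of 7 (camera adjusted p = 0.000882; adjusted p = 0.0782 with an estimated correlation). The count was 247 and 256 without salivary gland cNK replicates 2 and 1, and 259 without spleen cNK replicate 1; DESeq2 called 1234 and no low-count filter 1032, and the compared groups alone did not call Tnfsf10 (0.0847).

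Uterus cNK differed from spleen cNK in 291 genes, 245 higher and 46 lower. Rgs1 was higher at 1379 ± 352 CPM (log2 fold change 3.04 ± 0.211, adjusted p = 3.07e-05), and so were Ccl4 (1781 ± 454 against 751.3 ± 42.2 CPM, 1.25 ± 0.21, adjusted p = 0.00877) and Socs1 (2.52 ± 0.361, adjusted p = 0.00264). Immediate early and NF-kB, NFAT and AP-1 target genes had 9 of 32 higher and 0 lower, or 14 and 0 adjusted over the list alone (camera adjusted p = 6.33e-09; adjusted p = 0.0836 with an estimated correlation). The cAMP-responsive repressor gene Crem (2.14 ± 0.361) and the NF-kB cofactor gene Bcl3 (3.35 ± 0.589) were examples. Heat shock genes had 3 of 12 higher, or 10 adjusted over the list alone (camera adjusted p = 5.96e-06; adjusted p = 0.181 with an estimated correlation), including the mitochondrial chaperonin gene Hspe1 (1.83 ± 0.269, adjusted p = 0.00335). Cell cycle genes had 2 of 22 higher, or 5 adjusted over the list alone (camera adjusted p = 6.33e-09; adjusted p = 0.263 with an estimated correlation), and the cyclin gene Ccna2 stood at 61.6 ± 5.72 against 0.825 ± 0.284 CPM (6.21 ± 0.846). The checkpoint gene Vsir was lower (-1.98 ± 0.342, adjusted p = 0.0101). B and plasma cell markers had 3 of 12 lower, or 5 adjusted over the list alone (camera adjusted p = 2.2e-08; adjusted p = 0.011 with an estimated correlation), with Igkc at -6.79 ± 0.955. The count was 178 without spleen cNK replicate 1; DESeq2 called 1023, no low-count filter 872 and the compared groups alone 60, without Crem (0.0506), Bcl3 (0.0747), Socs1 (0.0967), Ccl4 (0.105) and Vsir (0.109).

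The ex vivo experiment was read first in unstimulated liver cells, which ask the liver question in a second set of libraries. Levels of some NK genes in these cells lay far from those of the panel, as given below. Of 19 residency and ILC1 markers 17 were higher and 2 lower in trNK (camera adjusted p = 1.71e-06; adjusted p = 0.0429 with an estimated correlation), and of 13 tested circulating and mature NK markers 0 were higher and 11 lower (camera adjusted p = 0.00033; adjusted p = 0.0322 with an estimated correlation). With the spread of the tissue panel 10 and 8 of these calls held. Itga1 was higher by 3.20 ± 0.142 (adjusted p = 5.75e-19), Tnfsf10 by 3.19 ± 0.0858 (adjusted p = 1.63e-24) and the NK receptor gene Cd160 by 2.58 ± 0.0906 (adjusted p = 1.61e-21). Il21r stood at 111.8 ± 13.5 CPM in trNK and 8.05 ± 0.402 CPM in cNK (3.80 ± 0.114), and the chemokine gene Xcl1 at 1993 ± 61.0 against 462 ± 6.38 CPM (2.11 ± 0.0476, adjusted p = 1.92e-26). Lower in trNK were Eomes (0.0302 ± 0.0427 against 65.0 ± 4.02 CPM), Klra4 (-6.02 ± 0.0836), Itga2 (-3.75 ± 0.104) and Prf1 (-1.88 ± 0.0491). All genes named so far in this paragraph were also called with the panel spread. Checkpoint receptors had 9 higher and 1 lower of 12 (camera adjusted p = 0.00326; adjusted p = 0.0461 with an estimated correlation). Interferon-stimulated genes had 26 higher and 1 lower of 28, or 27 and 1 adjusted over the list alone (camera adjusted p = 6.53e-09; adjusted p = 0.0115 with an estimated correlation), of which 4 held with the panel spread. Ifit1, an interferon-induced antiviral gene, was higher by 5.03 ± 0.096 in the main test and was not called with the panel spread (adjusted p = 0.633). Ifng was at 14900 ± 492 CPM in trNK and 12300 ± 386 CPM in cNK (adjusted p = 0.0575; DESeq2 adjusted p = 0.0179). Hepatocyte markers had 6 higher and 4 lower of 15 (camera adjusted p = 0.433), and their summed level was 593.2 and 560 CPM in trNK against 141.7 and 142.2 CPM in cNK. Adjusted over the list alone, no other count of this paragraph moved. In all, 10849 of 15959 genes differed, and 1695 with the panel spread, 704 higher and 991 lower.

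The liver trNK-cNK differences of the 2 experiments were set side by side over 14076 genes tested in both. Of 451 genes called in the panel, 337 had the same sign ex vivo. Genes higher in both numbered 150, where independent lists would share 67.6, and genes lower in both 163 against 96.4. Of the panel calls, 26 higher ones were called lower ex vivo and 53 lower ones were called higher. Abundant genes are more readily called in both experiments, so the numbers for independent lists are no chance level. The log2 fold changes correlated across genes with Pearson r = 0.144 and Spearman rho = 0.133; genes are not independent replicates. Il18r1 differed in direction between the experiments, lower in trNK of the panel and higher ex vivo by 0.59 ± 0.0994 (adjusted p = 3.71e-06), a call lost with the panel spread (adjusted p = 0.549). The lower Il18rap of panel liver trNK (130 and 70.7 against 689.5 and 692.2 CPM) was not seen ex vivo either. It stood at 354.8 and 365.2 CPM in unstimulated trNK and at 349.7 and 363.1 CPM in unstimulated cNK. The 2 experiments also differed in sex-linked transcripts: Xist was at 114.3 CPM or more in every panel library and at most 0.468 CPM ex vivo, whereas Ddx3y was at most 0.085 CPM in the panel and at least 85.2 CPM ex vivo.

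The response to PI, which activates protein kinase C and calcium signalling, was measured against unstimulated cells in cNK. The labels give these no treatment and do not say whether they were cultured, so the comparisons with them may also hold culture and Brefeldin A. Immediate early and NF-kB, NFAT and AP-1 target genes rose, with 23 higher and 5 lower of 33 (camera adjusted p = 0.000898; adjusted p = 0.155 with an estimated correlation). The NF-kB subunit gene Nfkb1 rose by 1.52 ± 0.0459 (adjusted p = 6.98e-23), and the early transcription factor genes Egr2 by 6.94 ± 0.14 and Nr4a1 by 3.32 ± 0.0679. Cytokine and chemokine genes had 17 higher and 4 lower of 28 (camera adjusted p = 0.000898; adjusted p = 0.155 with an estimated correlation). Ccl4 rose from 21360 ± 155 to 87920 ± 2556 CPM (2.04 ± 0.0353, adjusted p = 8.71e-29), Xcl1 by 2.58 ± 0.0484, Csf2, which encodes GM-CSF, from 126.3 ± 3.82 to 973.4 ± 31.9 CPM and Il2 from 0.162 ± 0.117 to 27.0 ± 0.357 CPM. Interferon-stimulated genes fell, with 3 higher and 24 lower of 28 (camera adjusted p = 6.77e-05; adjusted p = 0.0728 with an estimated correlation). The guanylate-binding protein gene Gbp2 changed by -3.34 ± 0.0891 and the transcription factor gene Irf1 by -1.30 ± 0.0766. The granule genes went apart, with Gzmb at 0.48 ± 0.0365, Gzma at -0.89 ± 0.045 and the protease gene Ctsw at -1.33 ± 0.0644. Unfolded protein response genes had 12 higher and 8 lower of 22 (camera adjusted p = 0.39). Hepatocyte markers had 3 higher and 8 lower of 15 (camera adjusted p = 0.39), with a summed level of 141.7 and 142.2 CPM before and 57.8 and 58.9 CPM after PI. Erythroid and platelet markers had 1 and 4 of 9 (camera adjusted p = 0.39), with 3316 and 3134 CPM before and 2104 and 1973 CPM after. Summed other ILC markers were at 569.8 and 586.7 CPM before and 187.9 and 195.1 CPM after. Adjusted over the list alone, no count of this paragraph moved. With the panel spread, Ccl4, Xcl1, Nfkb1, Gbp2, Irf1 and Ctsw stayed called, and Csf2, Il2, Egr2, Nr4a1, Gzmb and Gzma did not. In all, 10756 genes changed, and 1376 with the panel spread, 494 higher and 882 lower.

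In trNK, PI raised 22 and lowered 5 of the 33 immediate early and NF-kB, NFAT and AP-1 target genes (camera adjusted p = 0.00649; adjusted p = 0.178 with an estimated correlation). Egr1 rose by 4.73 ± 0.147 (adjusted p = 1.06e-22), the NF-kB subunit gene Rel by 2.28 ± 0.0575 and Nfkb1 by 1.58 ± 0.0458. Of 28 cytokine and chemokine genes 12 rose and 11 fell (camera adjusted p = 0.795). Ccl4 rose from 11690 ± 132 to 103700 ± 485 CPM (3.15 ± 0.0369, adjusted p = 1.33e-33) and Ccl3 from 815.2 ± 22.9 to 20380 ± 639 CPM (4.64 ± 0.0673), while Csf2 rose by 2.18 ± 0.0479 and Gzmb by 1.44 ± 0.0371, from 15070 ± 95.1 to 40970 ± 277 CPM. Ifng fell from 14900 ± 492 to 9851 ± 703 CPM (-0.60 ± 0.115, adjusted p = 0.00113). Il6 was at least 385.2-fold higher, at 30.1 ± 0.348 CPM. Il18rap fell by -1.88 ± 0.0602, Il18r1 by -1.44 ± 0.103 and the adaptor gene Myd88 by -2.76 ± 0.0941. The 23 IL-18 and MyD88 pathway genes did not pass as a list, with 10 higher and 9 lower, the same adjusted over the list alone (camera adjusted p = 0.999), a median log2 fold change of 0.01 and a mean of -0.85. Interferon-stimulated genes had 2 higher and 19 lower of 28, or 2 and 20 adjusted over the list alone, with Gbp2 at -1.71 ± 0.0735. With the panel spread the calls of Ccl4, Ccl3, Egr1, Rel, Nfkb1, Il6, Gbp2, Il18rap, Il18r1 and Myd88 held, and those of Csf2, Gzmb and Ifng did not. Hepatocyte markers moved with PI in trNK, with 1 higher and 10 lower of 15 and a summed level of 593.2 and 560 CPM before and 219.7 and 194.6 CPM after. Of 7 B and plasma cell markers 1 was higher and 5 lower (camera adjusted p = 0.176), with 816.9 and 725.9 CPM before and 281.6 and 247.5 CPM after, and the counts of these 2 lists did not move adjusted over the list alone. Summed other ILC markers were at 507.8 and 522.9 CPM before and 236 and 238.6 CPM after. In all, 10467 genes changed, and 1810 with the panel spread, 862 higher and 948 lower.

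Whether PI acted differently on trNK and cNK was tested as an interaction. Ccl4 rose more in trNK by 1.11 ± 0.0482 on the log2 scale (adjusted p = 3.14e-18) and Gzmb by 0.96 ± 0.0516 (adjusted p = 3.61e-16). Prf1 had an interaction of 1.12 ± 0.0677 (adjusted p = 5.24e-15): it rose from 227.9 ± 2.83 to 313 ± 3.08 CPM in trNK and fell from 838.4 ± 9.45 to 530.9 ± 2.22 CPM in cNK. Csf2 rose less in trNK (-0.76 ± 0.066, adjusted p = 1.54e-11), and Ifng had an interaction of -0.98 ± 0.162 (adjusted p = 0.00055). Irak2, a kinase-like gene of IL-1 and IL-18 receptor signalling (chromosome 6, 113638467 to 113695026), differed by 1.95 ± 0.128 (adjusted p = 2.96e-14), at 86.1 ± 2.1 CPM in trNK and 6.58 ± 0.147 CPM in cNK after PI. Of these 6 genes only Irak2 was called with the panel spread (adjusted p = 0.0468). Cytokine and chemokine genes had 3 positive and 17 negative interactions of 28, and interferon-stimulated genes 17 positive and 4 negative of 28 (camera adjusted p = 0.165), or 18 and 4 adjusted over the list alone. The PI responses of the cell types correlated across 15959 genes with Pearson r = 0.1, and with r = 0.686 across the 1537 genes with a mean above 100 CPM. With the panel spread, 127 genes were higher in both where independent lists would share 26.7, and 234 lower in both against 52.4; 123 went in opposite directions against 77. In the main test these counts were 2584 against 1700, 2612 against 1830 and 2439 against 3530. The opposite ones thus lay above the expected number with the panel spread and below it in the main test. The lists of both cell types used the same gene-wise spread, so genes with a small spread are readily called in both. The numbers for independent lists are therefore no chance level. In all, 8389 genes had an interaction, and 1228 with the panel spread, 666 positive and 562 negative.

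**Figure D3:**
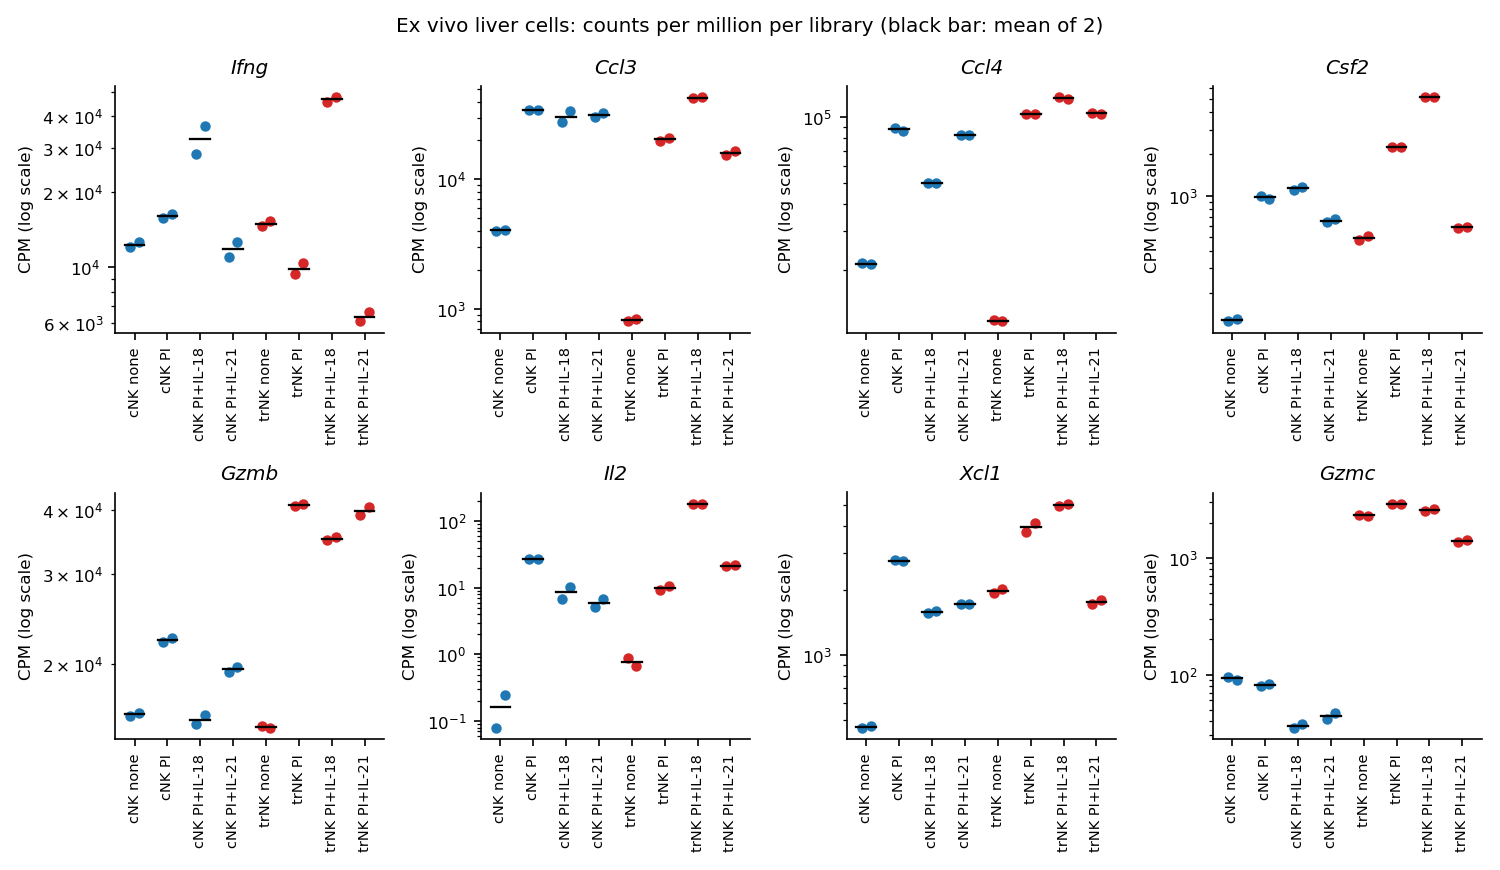
CPM (log axis, scaled with TMM factors) of 8 cytokine and granule genes in each ex vivo library, 2 dots per group with their mean as a black bar, cNK in blue and trNK in red. Mean Ifng was 46650 CPM in trNK with PI and IL-18 and 6347 CPM with PI and IL-21, and mean Csf2 was 5147 and 590.6 CPM.

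The cell types were also compared with each other after PI. Interferon-stimulated genes were higher in trNK, with 26 higher and 0 lower of 28 (camera adjusted p = 3.16e-11; adjusted p = 0.00528 with an estimated correlation), of which 8 held with the panel spread, Gbp2 among them (104.3 ± 6.41 against 8.45 ± 0.55 CPM, 3.62 ± 0.0893, adjusted p = 1.96e-25). Residency and ILC1 markers had 17 higher and 1 lower of 19 (camera adjusted p = 1.82e-06; adjusted p = 0.0325 with an estimated correlation), and circulating and mature NK markers 0 and 12 of 13 (camera adjusted p = 2.34e-05; adjusted p = 0.0147 with an estimated correlation). Cell cycle genes had 3 higher and 16 lower of 22 (camera adjusted p = 0.000988; adjusted p = 0.0278 with an estimated correlation), with the mitotic kinase gene Cdk1 at least 190.6-fold lower. Glycolysis genes had 1 higher and 14 lower of 17 (camera adjusted p = 0.00677; adjusted p = 0.356 with an estimated correlation). Irak2 was higher by 3.71 ± 0.0972 (adjusted p = 9.29e-25), Il21r by 3.53 ± 0.116, Cd160 by 3.29 ± 0.0993 and the Ikaros family gene Ikzf3 by 2.29 ± 0.073. The cytokine gene Osm was lower in trNK by -7.12 ± 0.161 (0.727 ± 0.0105 against 101.9 ± 0.791 CPM). Cdk1 and these 5 genes also held with the panel spread. Gzmb was higher by 0.88 ± 0.0367 (40970 ± 277 against 22280 ± 327 CPM), granzyme C (Gzmc) by 5.15 ± 0.06 and Csf2 by 1.21 ± 0.0465, and none of these 3 held with it (adjusted p = 0.468, 0.0936 and 0.725). Hepatocyte markers had 3 higher and 7 lower of 15 (camera adjusted p = 0.654), and their summed level was 219.7 and 194.6 CPM in trNK against 57.8 and 58.9 CPM in cNK. Erythroid and platelet markers had 5 and 2 of 9 (camera adjusted p = 0.426; median 0.57, mean -1.15), with 3415 and 3072 against 2104 and 1973 CPM. T cell markers had 5 and 4 of 10 (camera adjusted p = 0.738), with 1430 and 1337 against 844.3 and 848.7 CPM, and B and plasma cell markers 1 and 5 of 7 (camera adjusted p = 0.283), with 281.6 and 247.5 against 464.8 and 489.2 CPM. Adjusted over the list alone, no count of this paragraph moved. In all, 10547 genes differed, and 1649 with the panel spread, 836 higher and 813 lower.

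IL-18 signals through MyD88 and was added to PI to ask what it changes beyond PI. Changes with IL-18 or IL-21 may be indirect, through other cells of the liver suspension, which was not tested. In cNK, IL-18 and MyD88 pathway genes had 14 higher and 3 lower of 23 (camera adjusted p = 0.051). Irak2 rose by 2.86 ± 0.0966 (adjusted p = 1.05e-20), from 6.58 ± 0.147 to 48.0 ± 5.32 CPM. Tbx21 rose by 1.43 ± 0.09 (adjusted p = 1.11e-14), the glycolysis gene Pkm by 1.29 ± 0.0546 (adjusted p = 1.37e-18) and Ifng by 1.01 ± 0.116, from 16070 ± 417 to 32390 ± 5798 CPM (adjusted p = 3.26e-05). Ccl4 fell from 87920 ± 2556 to 50130 ± 38.8 CPM (-0.81 ± 0.0342) and Gzmb by -0.52 ± 0.0365. Of 20 other NK receptors and adaptors 0 rose and 17 fell (camera adjusted p = 0.000104; adjusted p = 0.152 with an estimated correlation), among them Klrd1, which encodes CD94 (-1.56 ± 0.0632), and the adaptor gene Tyrobp (-1.47 ± 0.0486). Residency and ILC1 markers had 2 higher and 15 lower of 19 (camera adjusted p = 0.0165; adjusted p = 0.152 with an estimated correlation), and cytotoxic granule and death ligand genes 1 and 12 of 17 (camera adjusted p = 0.0207; adjusted p = 0.152 with an estimated correlation). Erythroid and platelet markers moved with this group, with 1 higher and 6 lower of 9 and a summed level of 503.6 and 459.1 CPM against 2104 and 1973 CPM with PI. T cell markers had 1 and 7 of 10, with 625.3 and 639.2 against 844.3 and 848.7 CPM, and hepatocyte markers 2 and 8 of 15, with 42.5 and 39.0 against 57.8 and 58.9 CPM. The share of rRNA was 0.778% and 0.78% of counts against 1.6% and 1.52% with PI. Adjusted over the list alone, no count of this paragraph moved. With the panel spread Irak2, Tbx21, Pkm, Klrd1 and Tyrobp held, and Ifng, Ccl4 and Gzmb did not. In all, 10538 genes changed, and 785 with the panel spread, 477 higher and 308 lower.

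In trNK, IL-18 raised cytokine and chemokine genes, with 19 higher and 6 lower of 28 (camera adjusted p = 0.00445; adjusted p = 0.166 with an estimated correlation). Ifng rose from 9851 ± 703 to 46650 ± 1348 CPM (2.24 ± 0.12, adjusted p = 9.74e-08). Csf2 rose from 2251 ± 21.0 to 5147 ± 4.62 CPM (1.19 ± 0.0463), Il2 from 9.93 ± 1.00 to 181.7 ± 0.686 CPM (4.19 ± 0.138) and the anti-inflammatory cytokine gene Il10 from 0.181 ± 0.0831 to 16.4 ± 0.172 CPM. IL-18 and MyD88 pathway genes had 15 higher and 4 lower of 23 (camera adjusted p = 0.0236; adjusted p = 0.164 with an estimated correlation), with Myd88 at 1.95 ± 0.095 (adjusted p = 3.39e-17). The receptor gene Il18r1 (chromosome 1, 40465552 to 40500854) fell by 2.13 on the log2 scale (SE 0.119), Irf1 by 1.65 (SE 0.0815) and Prf1 by 0.90 (SE 0.0489). Interferon-stimulated genes had 4 higher and 21 lower of 28 (camera adjusted p = 0.0179; adjusted p = 0.166 with an estimated correlation). Neutrophil markers moved with this group: 8 of 9 rose and 1 fell (camera adjusted p = 0.000345; adjusted p = 0.0674 with an estimated correlation), and their summed level was 960.3 and 998.8 CPM against 7.81 and 9.02 CPM with PI. S100a9, a calcium-binding protein gene of neutrophils, rose by 7.08 ± 0.155, and Il1rn, the IL-1 receptor antagonist gene, was at least 1491-fold higher. Summed other ILC markers stood at 116.6 and 117.8 CPM against 236 and 238.6 CPM with PI. For hepatocyte markers the levels were 136.5 and 132.1 against 219.7 and 194.6 CPM. Erythroid and platelet markers had 2 higher and 5 lower of 9 (camera adjusted p = 0.419; median -1.17, mean 0.21), with a summed level of 1287 and 1227 CPM against 3415 and 3072 CPM with PI. Adjusted over the list alone, no count of this paragraph moved. With the panel spread Ifng (adjusted p = 0.0055), Myd88, Il18r1, Irf1, S100a9 and Il1rn held, and Csf2, Il2, Il10 and Prf1 did not. In all, 9579 genes changed, and 1318 with the panel spread, 542 higher and 776 lower.

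**Figure D4:**
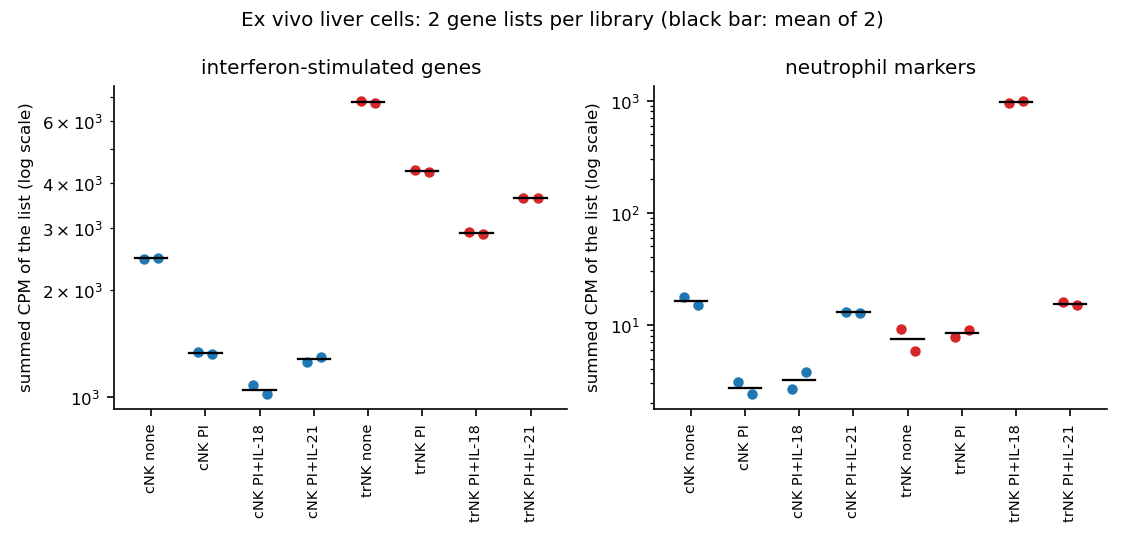
Summed CPM of library totals (log axis) of the 28 interferon-stimulated genes and of the 11 neutrophil markers in each ex vivo library, 2 dots per group with their mean as a black bar, cNK in blue and trNK in red. The neutrophil markers reached 960.3 and 998.8 CPM in trNK with PI and IL-18 and at most 17.6 CPM in every other library.

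The IL-18 responses of trNK and cNK differed in Irak2 by -4.04 ± 0.127 (adjusted p = 2.06e-21): it fell from 86.1 ± 2.1 to 38.0 ± 1.62 CPM in trNK and rose in cNK. Ccl4 differed by 1.05 ± 0.0481 (adjusted p = 1.19e-17), being 122600 ± 1436 against 103700 ± 485 CPM in trNK and lower with IL-18 in cNK. Il2 differed by 5.85 ± 0.191 (adjusted p = 4.5e-21), Tbx21 by -1.73 ± 0.131 (adjusted p = 8.08e-13) and Il18r1 by -2.02 ± 0.157 (adjusted p = 1.45e-12). The interaction of Ifng was 1.23 ± 0.163 (adjusted p = 0.000107). Irak2 and Tbx21 held with the panel spread (adjusted p = 4.75e-07 and 0.0442), and the other 4 genes did not. Cytokine and chemokine genes had 19 positive and 4 negative interactions of 28 (camera adjusted p = 0.00203; adjusted p = 0.295 with an estimated correlation), and other NK receptors and adaptors 17 and 0 of 20 (camera adjusted p = 0.00203; adjusted p = 0.455 with an estimated correlation), counts that did not move adjusted over the list alone. The responses correlated across 15959 genes with Pearson r = 0.01, and with r = 0.156 across the 1537 genes above 100 CPM. Calls with the panel spread gave 61 genes higher in both against 16.2 for independent lists, 71 lower in both against 15 and 109 opposite against 33.7. In the main test they were 1958 against 1720, 1596 against 1440 and 3151 against 3160. As with PI, both lists used the same gene-wise spread, so the numbers for independent lists are no chance level. In all, 8698 genes had an interaction, and 1132 with the panel spread, 398 positive and 734 negative.

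IL-21, a cytokine of the common gamma chain family, was added to PI to ask the same of cNK. Cytokine and chemokine genes fell, with 2 higher and 18 lower of 28, or 2 and 19 adjusted over the list alone (camera adjusted p = 0.023; adjusted p = 0.239 with an estimated correlation). Csf2 fell from 973.4 ± 31.9 to 658.3 ± 23.4 CPM (-0.56 ± 0.0461, adjusted p = 5.7e-12), Il2 from 27.0 ± 0.357 to 5.93 ± 1.15 CPM (-2.16 ± 0.141) and Xcl1 by -0.68 ± 0.0457. The early gene Fos changed by -2.02 ± 0.124 (adjusted p = 1.01e-14) and Eomes by -1.11 ± 0.118. The receptor gene Il21r rose from 6.29 ± 0.453 to 17.2 ± 2.09 CPM (1.47 ± 0.121, adjusted p = 6.64e-12) and Cd160 by 1.38 ± 0.102. Glycolysis genes had 1 higher and 14 lower of 17 (camera adjusted p = 0.023; adjusted p = 0.615 with an estimated correlation), with Tpi1 at -0.61 ± 0.05. Cell cycle genes had 4 higher and 15 lower of 22, or 5 and 15 adjusted over the list alone (camera adjusted p = 0.023; adjusted p = 0.142 with an estimated correlation). Hepatocyte markers moved with this group, with 0 higher and 9 lower of 15 (camera adjusted p = 0.023; adjusted p = 0.142 with an estimated correlation). Erythroid and platelet markers had 0 higher and 7 lower of 9, or 1 and 7 adjusted over the list alone, with a summed level of 946.3 and 894.4 CPM against 2104 and 1973 CPM with PI. Of the genes named here Fos held with the panel spread (adjusted p = 0.0283). In all, 9378 genes changed, and 976 with the panel spread, 434 higher and 542 lower.

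In trNK, IL-21 lowered Csf2 from 2251 ± 21.0 to 590.6 ± 4.45 CPM (-1.93 ± 0.0475, adjusted p = 2.97e-24) and the interferon-induced chemokine gene Cxcl10 from 1186 ± 32.5 to 216.6 ± 6.07 CPM (-2.45 ± 0.0517, adjusted p = 7.06e-26). Il18r1 fell from 40.5 ± 2.1 to 2.86 ± 0.493 CPM (-3.84 ± 0.145, adjusted p = 1.24e-19), Gzmc by 1.06 on the log2 scale (SE 0.0502) and Ifng from 9851 ± 703 to 6347 ± 382 CPM (adjusted p = 0.000896). Higher with IL-21 were the glucose transporter gene Slc2a3 (2.12 ± 0.128, adjusted p = 4.43e-15), the kinase gene Irak4 (2.96 ± 0.146), the checkpoint gene Ctla4 (472.4 ± 16.4 against 231.7 ± 9.75 CPM, 1.03 ± 0.0597) and Il10 (4.79 ± 0.432). Socs3, a cytokine signalling inhibitor gene, did not pass the test (adjusted p = 0.166). Erythroid and platelet markers had 0 higher and 5 lower of 9, the same adjusted over the list alone (camera adjusted p = 0.174), with a summed level of 938.1 and 917.4 CPM against 3415 and 3072 CPM with PI. No list reported here passed the camera test in this comparison. Il18r1, Slc2a3 and Irak4 held with the panel spread, and Csf2, Cxcl10, Gzmc, Ifng, Ctla4 and Il10 did not. In all, 9437 genes changed, and 1162 with the panel spread, 546 higher and 616 lower.

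The IL-21 responses of trNK and cNK differed in Il18r1 by -3.66 ± 0.182 (adjusted p = 7.24e-17), which stood at 37.3 ± 2.70 against 42.4 ± 0.111 CPM in cNK. Slc2a3 differed by 3.35 ± 0.181 (adjusted p = 4.11e-16) and Irak4 by 2.90 ± 0.206 (adjusted p = 2.04e-13). Csf2 fell more in trNK (-1.37 ± 0.0653, adjusted p = 3.29e-17), and Il21r differed by -1.43 ± 0.154 (adjusted p = 1.94e-09), being at 74.7 ± 0.436 against 72.7 ± 5.65 CPM in trNK. Il18r1, Slc2a3 and Irak4 held with the panel spread, and Csf2 and Il21r did not (adjusted p = 1 and 0.399). Glycolysis genes had 11 positive and 1 negative interactions of 17 (camera adjusted p = 0.032; adjusted p = 0.999 with an estimated correlation), a count that did not move adjusted over the list alone. The responses correlated across 15959 genes with Pearson r = -0.024, and with r = 0.052 across the 1537 genes above 100 CPM. The panel spread gave 58 genes higher in both against 14.8 for independent lists, 67 lower in both against 20.9 and 144 opposite against 35.3. In the main test they were 1485 against 1310, 1630 against 1470 and 2957 against 2770. Here too the gene-wise spread was shared by both lists, and independent lists give no chance level. In all, 8222 genes had an interaction, and 1209 with the panel spread, 615 positive and 594 negative.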

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

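The tests of explanations in this part were chosen only after the results were seen, except the thinning of the ex vivo libraries, whose prediction was written down before. The results of the next paragraph stand here because an interaction test found a difference between organs or between cell types. The 3 patterns after it were met while reading the libraries and were chosen for weighing without such a test.

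Between salivary glands and liver the trNK-cNK difference differed in 56 genes, with Klra4 at 10.74, Eomes at 7.55, Zeb2 at 4.50, Il18r1 at 2.43 and Cxcr3 at -3.77. Between uterus and liver it differed in 107 genes, with Klra4 at 11.51, Eomes at 9.04, Cenpa at 3.37, Thy1 at 2.62, Ccl4 at -1.88, Klrc1 at -2.37 and Itgb7 at -3.84. The response to PI differed between trNK and cNK in 8389 genes, with Irak2 at 1.95, Prf1 at 1.12, Ccl4 at 1.11, Gzmb at 0.96, Csf2 at -0.76 and Ifng at -0.98. The IL-18 response differed in 8698 genes, with Il2 at 5.85, Ifng at 1.23, Ccl4 at 1.05, Tbx21 at -1.73, Il18r1 at -2.02 and Irak2 at -4.04. The IL-21 response differed in 8222 genes, with Slc2a3 at 3.35, Irak4 at 2.90, Csf2 at -1.37, Il21r at -1.43 and Il18r1 at -3.66. With the spread of the tissue panel the last 3 counts were 1228, 1132 and 1209.

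The 2 libraries of each ex vivo group lay far closer together than those of the panel. Deeper sequencing was excluded as the cause: thinned to the panel's median total of 20.8 M counts, the ex vivo coefficient of variation was 0.067, against 0.848 in the panel. Absence was counted as under 1 CPM, among 4201 genes at 20 CPM or more in all panel libraries. Such genes absent from a library were absent from its partner 2.56 times as often as from libraries of another treatment (91.6% against 35.8%). This would follow if both libraries came from 1 pool of cells or 1 amplified cDNA. Treatment effects shared by both libraries would raise this ratio too, so it may not separate the 2 causes. No biological explanation was tested.

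Ifng was already high in unstimulated ex vivo cells and fell with PI in trNK. An exchange of labels was excluded, since of 33 immediate early and related target genes 23 rose and 5 fell with PI in cNK, and 22 rose and 5 fell in trNK. A larger share of abundant transcripts was excluded too: with the 10 most abundant other genes left out of each total, Ifng in PI over unstimulated trNK was 0.655. The lowest unstimulated library held 34.5 times the Ifng of the highest fresh liver library, so isolation and culture could have raised it. The 2 experiments also differ in sex-linked transcripts and handling, and the question stayed open.

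Neutrophil genes stood high in both trNK libraries given PI and IL-18. Of 11 listed markers, 7 were at least 10 times higher there than in every other ex vivo library, led by S100a8 (635.3 and 639.9 CPM against at most 14.7) and S100a9 (241.9 and 270.8 CPM against at most 6.36), which RNA of neutrophils could produce. Of these 7, Csf3r (2.68 and 3.39 CPM), Ltf (2.107 and 3.23 CPM) and Mmp8 (0.683 and 1.02 CPM) stayed low. Of the other 4, Ly6g and Cxcr2 had no counts in these 2 libraries, Mmp9 had none against at most 5.33 CPM elsewhere, and Camp stood at 3.7 and 5.41 CPM against at most 1.85. A general rise in RNA of other liver cells was not seen. Of 4 lists (macrophage, B cell, hepatocyte and erythroid), 0 were at least 2 times higher in both libraries than in every other trNK library. The test cannot exclude contamination common to the trNK libraries. Erythroid and platelet markers stood at 1227 and 1287 CPM in these 2 libraries and at up to 3415 CPM in the other trNK libraries. A response of the trNK themselves could not be told apart, with 8 markers called higher with IL-18 in trNK. The labels state no gate that would remove neutrophils, and whether Il1rn and Il10 came from the same cells was not tested.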

How the results depend on the processing

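The spread of the tissue panel was chosen only after the data were seen. In the tissue panel, counts moved by over 1.5 times and no gene call changed sign under any setting; the cause was not tested. DESeq2 gave 1202 genes for trNK against cNK in liver, 284 in salivary glands and 679 in uterus; 405, 610 and 115 for the interactions of salivary glands with liver, uterus with liver and uterus with salivary glands; 278, 1234 and 1023 for cNK of liver, salivary glands and uterus against spleen; and 75 genes shared by 3 organs. It kept 466 of 468, all 45 and all 189 calls of the first 3 comparisons. Without the low-count filter, in the same order, the counts were 1012, 297, 533, 419, 544, 151, 291, 1032, 872 and 102. The compared groups alone, with fewer libraries to measure the spread, gave 187, 26, 0, 35, 53, 1, 0 and, for uterus against spleen, 60, with 0 genes shared by 3 organs. RLE size factors moved no count by over 1.5 times.

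Differences between replicates correlated at -0.0293 to 0.0864 between groups of the panel and at -0.0149 to 0.0575 ex vivo. Such low values over all genes show no broad pairing by replicate number but cannot exclude a shared batch. The highest was that of uterus cNK and trNK. In both, Mucl2 was higher in replicate 1 (136.6 and 56.03 CPM) than in replicate 2 (0 and 0.3547 CPM). The replicate number as a block gave 71 genes for the interaction of uterus with liver, without Thy1 (adjusted p = 0.0529), and 2 for liver against spleen cNK, 1 of them among the 13 of the main fit and without Rgs1, Lilr4b and Ppp1cc (0.0691, 0.051 and 0.051). It did not call Tnfsf10 in salivary glands (0.0564), called Ifng between unstimulated trNK and cNK (0.000534), and moved no other count by over 1.5 times.

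Leaving out 1 library left a group with 1, which was assumed to vary like the other groups. Counts then ran from 336 to 514 in liver, 30 to 118 in salivary glands, 126 to 441 in uterus, 47 to 156, 90 to 318 and 0 to 51 for the 3 interactions, and 39 to 108, 247 to 348 and 178 to 324 for liver, salivary gland and uterus cNK against spleen; 16 to 23 genes were shared by 3 organs. Ex vivo they ran from 10013 to 10355 (unstimulated), 9873 to 10212 (PI, cNK), 9848 to 9984 (PI, trNK), 7940 to 8085 (PI interaction), 9869 to 9990 (trNK against cNK after PI), 9700 to 9985 (IL-18, cNK), 8965 to 9005 (IL-18, trNK), 8290 to 8450 (IL-18 interaction), 8346 to 8740 (IL-21, cNK), 8775 to 8906 (IL-21, trNK) and 7710 to 7872 (IL-21 interaction).

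With the panel spread, which is wider (0.848 against 0.0756), the ex vivo counts were, in that order, 1695, 1376, 1810, 1228, 1649, 785, 1318, 1132, 976, 1162 and 1209. Of 99 named ex vivo results 55 kept their side of the threshold with it. The correlation of the liver difference between experiments ran from 0.101 to 0.217. Of the list calls, 13 of the panel and 8 ex vivo held with an estimated correlation, and 20 and 26 did not. In the panel, where 2-fold changes were recovered in 8% of simulated liver genes, the spread between 2 libraries limits small changes.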

Other observations

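Further gene groups were measured in liver trNK against cNK of the tissue panel. Lymphocyte transcription factors had 2 higher and 5 lower of 23, or 5 and 7 adjusted over the list alone (camera adjusted p = 0.111), and Zeb2 and Eomes were among the lower ones. T cell markers had 2 higher and 1 lower of 11, or 3 and 3 adjusted over the list alone (camera adjusted p = 0.185). Other ILC markers had 0 higher and 1 lower of 7 (camera adjusted p = 0.132). Cholesterol synthesis genes had 1 higher and 0 lower of 19; adjusted over the list alone, the counts of these last 2 lists did not change.

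Some libraries of 1 group differed in markers of other cells. Summed erythroid and platelet markers stood at 1482 CPM in liver trNK replicate 1 and 20.3 CPM in replicate 2, and B and plasma cell markers at 664.5 and 2540 CPM. Mucl2, a gene of salivary secretion, stood at 16320 to 30760 CPM in the salivary gland libraries and at most 136.6 CPM in the other panel libraries. In the 3 chromatin accessibility samples nothing was measured here, and 2 of them carry a title that contradicts their source.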
